A study of Mus musculus with 16 samples.

How the data were processed

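Liver RNA of 16 C57BL/6J mice was analysed, in 4 groups of 4 libraries formed by sex and by the gene carried by an adeno-associated virus of serotype 8. The vector expressed either the liver isoform of pyruvate kinase (PKLR) or green fluorescent protein (GFP) from a hepatocyte-directed promoter. Per the labels, mice were injected at 8 weeks of age, fed a diet high in fat and sucrose, and sampled at 16 weeks. Per the labels' protocols, frozen liver was homogenised, total RNA with an integrity value above 7 was taken, and libraries were made with a stranded Illumina kit for total RNA. The deposited table holds raw read counts per gene for the 16 libraries, which are whole numbers. HISAT2, DESeq2 and the builds GRCm38 and mm10 are named, without versions, in the submitters' processing notes. The counting program, the annotation release, the strand setting and the treatment of reads that map to several places are not given in the sources used here.

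The table lists 27230 Ensembl gene identifiers, and 27035 of them matched a gene of GENCODE release M21 (GRCm38), from which symbols, biotypes, coordinates, transcript lengths and GC content were taken. The other 195 identifiers kept their Ensembl name and held 0.0464% to 0.0627% of the counts of a library. Total counts per library ran from 22846622 to 34412053. No gene in the table had a sum below 2 over all libraries. Replicates of a group differed by more than sampling noise in every pair, with a lowest chi-square per degree of freedom of 22.1, so each library was counted once. The labels describe 4 mice per group, and each library was treated as 1 mouse.

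Genes with low counts were removed with the filterByExpr function of edgeR 4.0.16 in R 4.3.3 (minimum count 10, minimum total 15), which left 16119 genes. Libraries were scaled by trimmed mean of M values (TMM), with factors from 0.861 to 1.11. One quasi-likelihood model with the 4 group means was fitted to all 16 libraries (glmQLFit and glmQLFTest with robust settings), so that groups shared 1 estimate of the spread. The common biological coefficient of variation was 0.171. Each standard error (SE) is the absolute log2 fold change over the square root of the F value. P-values were adjusted by Benjamini and Hochberg over all genes tested, and genes with an adjusted p under 0.05 are called. Levels are CPM (the cpm function of edgeR, counts relative to library size) on the TMM scale, given as mean ± standard deviation (SD) over 4 libraries. There were 5 comparisons: PKLR against GFP in males and in females, the difference between these effects (female minus male effect), and females against males within each vector.

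A total of 50 gene lists for metabolism, organelles, stress, immunity, cell types, hormone signalling and sex were written before the data were examined, and 48 of them had at least 4 genes tested. Each was tested against the other genes with camera in limma 3.58.1, on log2 CPM with a prior count of 2 and a preset correlation of 0.01, with adjustment over the 48 lists. Camera was repeated with the correlation between genes estimated from the data, and the fry test was run as an alternative, which tests whether a list moves one way and does not compare it with other genes. Members of each list were also adjusted over the list alone. Genes named in the text follow a rule also written before the data were examined. In each comparison it takes called genes whose 4 libraries of one group all lie above the 4 of the other and whose higher mean is at least 1 CPM. Of these it names the 8 with the largest rise, the 8 with the largest fall and the next 6 by p, leaving out genes known only by a number. It adds Pklr, Pkm and up to 4 members of each list with the smallest p. Where no gene is called it names the 6 smallest p in each direction, with values only. Genes outside the rule are said to be so, and some genes that the rule takes are not reported here. Folds against a group with 0 counts are lower bounds set by 3 counts over the group, and folds against a group with few counts carry an exact 95% interval, which covers counting error only.

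The procedure was tested on simulated counts, drawn from the means, spread and library sizes of the real libraries, with 200 genes and the members of 1 list changed. For PKLR in males 41.8% of genes changed 1.5-fold, 80.6% of those changed 2-fold and 97.0% of those changed 4-fold were recovered among 15888 genes tested. The same shares were 49.3%, 80.6% and 100% for PKLR in females (15909 genes), 2.99%, 53.7% and 87.9% for the interaction (15897 genes), 52.2%, 82.1% and 98.5% for sex with GFP (15950 genes), and 40.3%, 86.6% and 97.0% for sex with PKLR (15943 genes). False calls made up 3.68% to 6.36% of the calls over the 5 comparisons. Each gene was drawn independently, around 1 mean shared by all libraries apart from the planted changes. These rates therefore leave out correlation between genes and structure among the libraries, and may not hold for the real ones. A trend on GC content and length of the size seen in each real library was then added. False calls were 3.87%, 18.5%, 13.7%, 36.4% and 0.69% of calls in the same order. After the trend was removed they were 2.53%, 2.5%, 3.28%, 5.39% and 4.35%. The trend added was of the form that the correction fits, so its removal does not show that the correction works on the real libraries.

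Alternatives fixed before the data were examined were DESeq2 size factors in edgeR, upper-quartile factors, total counts, DESeq2 1.42.0, limma-voom, no filter on low counts, a filter of at least 1 CPM in 4 libraries, a fit to the compared groups alone, the replicate number as a block, a fit without Pklr and the 20 most abundant genes, and leaving out each library in turn. Chosen after seeing the data were a correction for GC content and transcript length, made as a spline with 4 inner knots per library and entered as offsets, and a fit without female GFP libraries 2, 3 and 4, which leaves 1 library in that group. Called processed pseudogenes were matched to coding transcripts with BLAST 2.17.0. Other splits of the same libraries into groups of 4 were counted for each comparison.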

Results

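RNA was sequenced from the livers of 16 mice that received a virus expressing PKLR, the pyruvate kinase of liver, or GFP as a control. The 4 groups were males with GFP, males with PKLR, females with GFP and females with PKLR, with 4 mice in each. The series asks, by its title, about roles of PKLR that depend on sex in fatty liver disease. Libraries held 22846622 to 34412053 counts. Xist, the RNA of the inactive X chromosome, lay between 538 and 909 CPM in every female and between 0.598 and 1.39 CPM in every male, and no library went against its label in sex or vector.

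Pklr (ENSMUSG00000041237, chromosome 3, 89136142 to 89146784 on the plus strand of GRCm38) was higher in every PKLR liver than in any GFP liver of the same sex. It rose from 219 ± 82.6 CPM to 998 ± 164 CPM in males (SD, n = 4 per group), a 4.55-fold change. In females it rose from 195 ± 56.8 CPM to 603 ± 182 CPM, a 3.09-fold change. The log2 fold changes were 2.19 (SE 0.279, adjusted p = 0.0131) and 1.63 (SE 0.274, adjusted p = 0.0287). The difference between the sexes in this effect was -0.56 (SE 0.378, adjusted p = 0.526). Pkm, the pyruvate kinase of most other tissues, had log2 fold changes of -0.10 in males (adjusted p = 0.826) and 0.42 in females (adjusted p = 0.241), and the male value was 0.02 when libraries were scaled to total counts. Counts of Pklr hold reads of the mouse gene together with any reads of the vector that map to it.

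**Figure D1:**
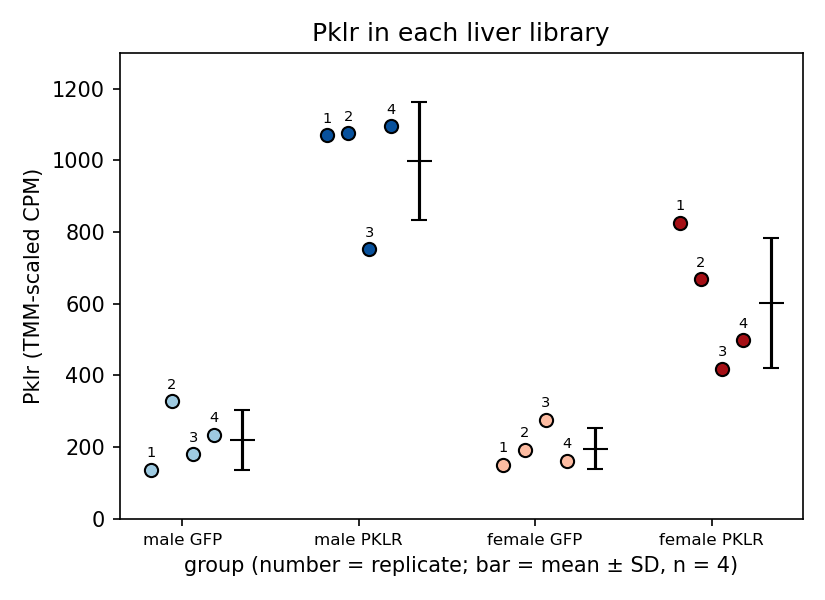
Pklr level in TMM-scaled CPM (vertical axis) for each library of the 4 groups (horizontal axis), with the replicate number beside each point and the mean ± SD of 4 libraries as a bar. PKLR livers average 998 CPM in males and 603 CPM in females, against 219 and 195 CPM with GFP.

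In males, Pklr was the 1 gene that passed the test with PKLR. Genes of amino acid breakdown and the urea cycle had 25 of 27 members below 0 and a median log2 fold change of -0.54. Genes of fatty acid oxidation and other targets of the lipid sensor PPAR-alpha had 32 of 35 members above 0 and a median of 0.21. No member of either list passed the test over all genes, and neither list passed with an estimated correlation (adjusted p = 0.534 and 0.651). The edgeR test called 1 gene higher and 0 lower, with 2110 genes at an unadjusted p under 0.05 where chance gives 806. Without 1 male library that number was 1121 (male GFP library 3) to 2821 (male GFP library 4). Genes are not independent, so such a number can exceed chance without an effect of PKLR. DESeq2 called 73 higher and 71 lower, and limma-voom called 1 higher and 0 lower. The 4 PKLR livers lay apart from the 4 GFP livers for 6.05% of genes, where chance gives 2.86%. No gene was called after the correction for GC content and length, where the smallest adjusted p was 0.0513, or without male GFP library 3, male PKLR library 2 or male PKLR library 4. Without the other male libraries there were 2 or 3 genes higher and 0 to 7 lower.

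Camera found 17 lists past the test in males, and none of them kept its call with an estimated correlation, where adjusted p-values were 0.534 to 0.701. The amino acid and urea cycle list had a camera adjusted p = 1.27e-10 and an adjusted p = 0.534 with an estimated correlation. Adjusted over the list alone, 18 members were lower. They included the aspartate transaminase Got1 (log2 fold change -1.72), the alanine-glyoxylate transaminase Agxt (-1.09) and the urea cycle enzymes Ass1 (-1.15) and Cps1 (-0.73), with adjusted p-values over all genes of 0.0857, 0.134, 0.228 and 0.228. Got1 averaged 225 ± 123 CPM with GFP and 68.4 ± 8.9 CPM with PKLR. Genes of hepatocytes near the portal vein, a list that shares Ass1 and Cps1 with it, had 15 of 16 members below 0 (median -0.53, camera adjusted p = 2.43e-06, adjusted p = 0.534 with an estimated correlation). Among the 8 members lower adjusted over the list alone were Aldh1b1 (-1.89, adjusted p = 0.154 over all genes) and Sox9 (-0.81, adjusted p = 0.216). Hepatocyte identity genes had a median of -0.30 (17 of 22 below 0, camera adjusted p = 0.00308, adjusted p = 0.534 with an estimated correlation). There were 4 lower adjusted over the list alone, with the plasma proteins Ahsg at -0.64 and transferrin (Trf) at -0.62, each with an adjusted p = 0.216 over all genes.

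Of the PPAR-alpha list, 5 members were higher when adjusted over the list alone. The fatty acid transporter Cd36 had a log2 fold change of 1.62, the pantetheinase Vnn1 1.28, the peroxisome protein Pex11a 0.71 and the isomerase Eci2 0.49, each with an adjusted p = 0.216 over all genes. The list had a camera adjusted p = 2.43e-06 and an adjusted p = 0.651 with an estimated correlation. Targets of NRF2, a regulator of antioxidant genes, had a median of 0.31 with 17 of 20 above 0 (camera adjusted p = 5.04e-05, adjusted p = 0.534 with an estimated correlation). The 7 members higher adjusted over the list alone included the glutathione synthesis gene Gclc (0.79), Gstm1 (0.73) and Txnrd1 (0.33), with adjusted p-values over all genes of 0.138, 0.216 and 0.228. Targets of p53 had a median of 0.37 (13 of 15 above 0, camera adjusted p = 0.000595, adjusted p = 0.534 with an estimated correlation). Of these 4 were higher and 1 lower adjusted over the list alone, with Eda2r at 1.51 (adjusted p = 0.234), Gdf15 at 1.17 (0.228) and Ccng1 at 0.42 (0.235) over all genes. Xenobiotic metabolism genes (median 0.15, camera adjusted p = 0.00699, adjusted p = 0.603 with an estimated correlation) had 4 members higher over the list alone, among them the receptor Nr1i3 (0.77, adjusted p = 0.187 over all genes) and the exporter Abcc3 (1.03, adjusted p = 0.216). Bile acid genes (median 0.11, camera adjusted p = 0.0263, adjusted p = 0.534 with an estimated correlation) also had 4 higher over the list alone, with Slco1b2 at 0.57 (adjusted p = 0.216 over all genes) and Abcc2 and Abcg5 at 0.51 and 0.70 (each 0.228).

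Ribosomal and respiratory chain genes lay mostly below 0 in PKLR males, by small amounts, and none passed. All 84 cytosolic ribosomal protein genes had negative values (median -0.24, camera adjusted p = 2.61e-14), as did 74 of 79 nuclear genes of the respiratory chain (median -0.24, camera adjusted p = 7.69e-12) and 72 of 74 genes of the mitochondrial ribosome (median -0.15, camera adjusted p = 7.05e-08). Each had an adjusted p = 0.651 with an estimated correlation, and 0 members were called adjusted over the list alone. Short genes stood 0.75 (log2) higher against long genes in male GFP library 3 than in the average library, and after correction for GC content and length the medians were -0.11, -0.12 and -0.11, against -0.13, -0.13 and -0.04 with total counts. Liver genes known to be higher in males had a median of -0.38 (23 of 26 below 0, camera adjusted p = 0.000261, adjusted p = 0.651 with an estimated correlation), with 1 higher and 2 lower adjusted over the list alone. Serpina1e of that list had a log2 fold change of -1.20 (adjusted p = 0.0948 over all genes) and belongs to a family of near-identical genes. The other lists past camera were histones of replication (median -0.37), lymphocyte markers (-0.67), proliferation (-0.25), sinusoidal endothelial markers (0.22) and X-inactivation genes (0.18), with adjusted p-values of 0.651, 0.651, 0.651, 0.701 and 0.55 with an estimated correlation. After correction for GC content and length the histone median was -0.19, and the camera calls of lymphocyte markers (median -0.55, adjusted p = 0.0623) and X-inactivation genes (median 0.09, adjusted p = 0.273) ended. Glycolysis without Pklr did not pass (8 of 21 members above 0, median -0.08, camera adjusted p = 0.636), and neither did fatty acid and triglyceride synthesis (10 of 26 above 0, median -0.16, camera adjusted p = 0.749). Targets of the glucose sensor ChREBP did not pass either (median -0.01, camera adjusted p = 0.127). Adjusted over that list alone, 4 members were higher, namely Klf10 (0.77), Txnip (0.91), Rgs16 (2.30) and Gpd1 (0.45), with adjusted p-values over all genes of 0.0794, 0.286, 0.228 and 0.259.

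In females, 44 genes rose and 85 fell with PKLR. Apart from Pklr, the genes that rose changed by small amounts and included Trim62 (log2 fold change 1.13), Zfp36l1-ps (0.97), the TGF-beta inhibitor Smad7 (0.93), the lipid transporter Abca7 (0.81), the kinase scaffold Ksr1 (0.80), the proton pump subunit Atp6v0c (0.78) and Rita1 (0.77), with adjusted p-values of 0.029 to 0.0451. C77080 (0.56) and the kinase Map3k11 (0.48) were among the smallest p-values. Of the genes that fell, 60 were processed pseudogenes, 9 were protein-coding, 5 were miscellaneous RNAs and 4 were mitochondrial transfer RNAs. Named among them were Serpina3e-ps (-2.45), Txn-ps1 (-1.77), Rps24-ps2 (-1.45), Rpl31-ps10 (-1.30) and Rdh18-ps (-0.77), the transfer RNAs mt-Tc (-1.47), mt-Tq (-1.38) and mt-Te (-1.08), and the coding genes Serpina3c (-1.43) and C1s2 (-1.13). Their adjusted p-values were 0.0284 to 0.0302. Reads of processed pseudogenes, and of Serpina3c and C1s2 with their close relatives, may belong to other copies, so these values are uncertain.

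Protein-coding genes that rose had a mean GC content of 57.9%, against 49.6% for all coding genes tested. GC-rich minus GC-poor genes lay at -0.34, -0.42 and -0.42 (log2) in female GFP libraries 2, 3 and 4, and the 60 called pseudogenes had medians of 1.27, 1.23 and 1.10 there. Female GFP library 1 had 0.07 and -0.12 on the same measures. The edgeR test called 0 genes after correction for GC content and length (1658 at an unadjusted p under 0.05), where the genes that fell kept a median of -1.10 of -1.45 (median adjusted p = 0.0718) and those that rose 0.27 of 0.54 (median adjusted p = 0.316). Correction for GC content alone gave 3 higher and 50 lower, and for length alone 36 and 51. Without female GFP library 1 it called 780 higher and 563 lower. No gene was called without female GFP library 2, 3 or 4 or female PKLR library 3 or 4, and 1 without female PKLR library 1. The fit to the females alone called 0 genes (2718 at an unadjusted p under 0.05). DESeq2 called 275 higher and 286 lower, and limma-voom 7 and 4. Scaling to total counts gave 230 higher and 100 lower in place of 44 and 85. The groups lay apart for 8.26% of genes, where chance gives 2.86%.

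**Figure D2:**
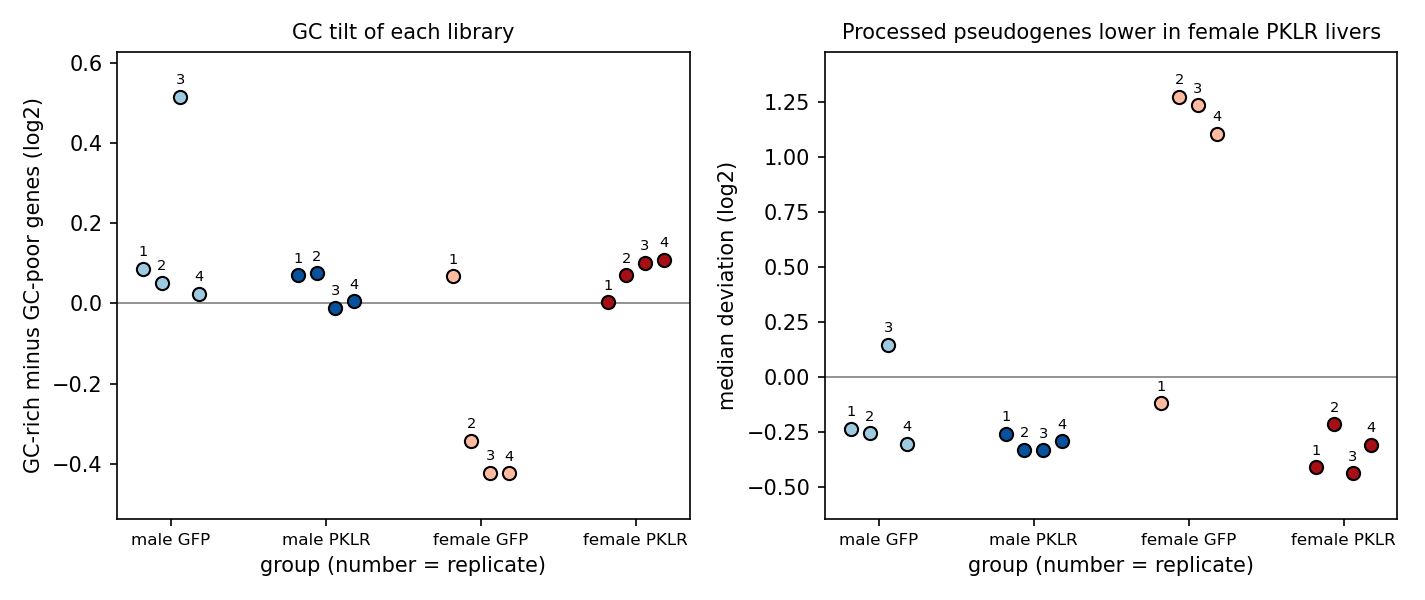
Left, median log2 deviation of GC-rich genes minus that of GC-poor genes in each library. Right, median log2 deviation of the 60 processed pseudogenes called lower in female PKLR livers. Groups are on the horizontal axis, with replicate numbers beside the points. Female GFP libraries 2, 3 and 4 lie at -0.34 to -0.42 on the left and at 1.10 to 1.27 on the right.

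Camera found 4 lists past the test in females, each with an adjusted p = 0.941 with an estimated correlation. Markers of sinusoidal endothelial cells had 17 of 18 above 0 (median 0.46, 0.28 after correction for GC content and length, camera adjusted p = 4.36e-06). The TGF-beta co-receptor Eng rose by 0.51 (adjusted p = 0.0312), and 9 members were higher adjusted over the list alone, with Gpr182 at 0.56, Stab1 at 0.49 and Flt4 at 0.52 (adjusted p = 0.0642, 0.0661 and 0.077 over all genes). Cholesterol synthesis genes had 25 of 26 below 0 (median -0.36, camera adjusted p = 7.56e-05). None was called adjusted over the list alone, and Stard4, Msmo1 and Cyp51 had values of -0.48, -1.16 and -0.88 (adjusted p = 0.299, 0.3 and 0.358). All 13 genes of the mitochondrial genome lay below 0 (median -0.24, camera adjusted p = 1.84e-05), with 4 lower adjusted over the list alone and mt-Nd6 at -0.52 (adjusted p = 0.052 over all genes). After correction for GC content and length their median was 0.03 and the camera adjusted p was 0.557. Liver genes known to be higher in females had 24 of 29 below 0 (median -0.34, camera adjusted p = 0.00805), with 0 called adjusted over the list alone, and Cyp3a41b and Cyp2b13 had values of -0.52 and -0.68 (adjusted p = 0.194 and 0.197). That call ended after the same correction (median -0.20, camera adjusted p = 0.0516) and without female PKLR library 3 (0.0943). Glycolysis without Pklr (15 of 21 above 0, median 0.12, camera adjusted p = 0.456), fatty acid and triglyceride synthesis (16 of 26 above 0, median 0.12, camera adjusted p = 0.705) and ChREBP targets (12 of 15 above 0, median 0.15, camera adjusted p = 0.183) did not pass.

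**Figure D3:**
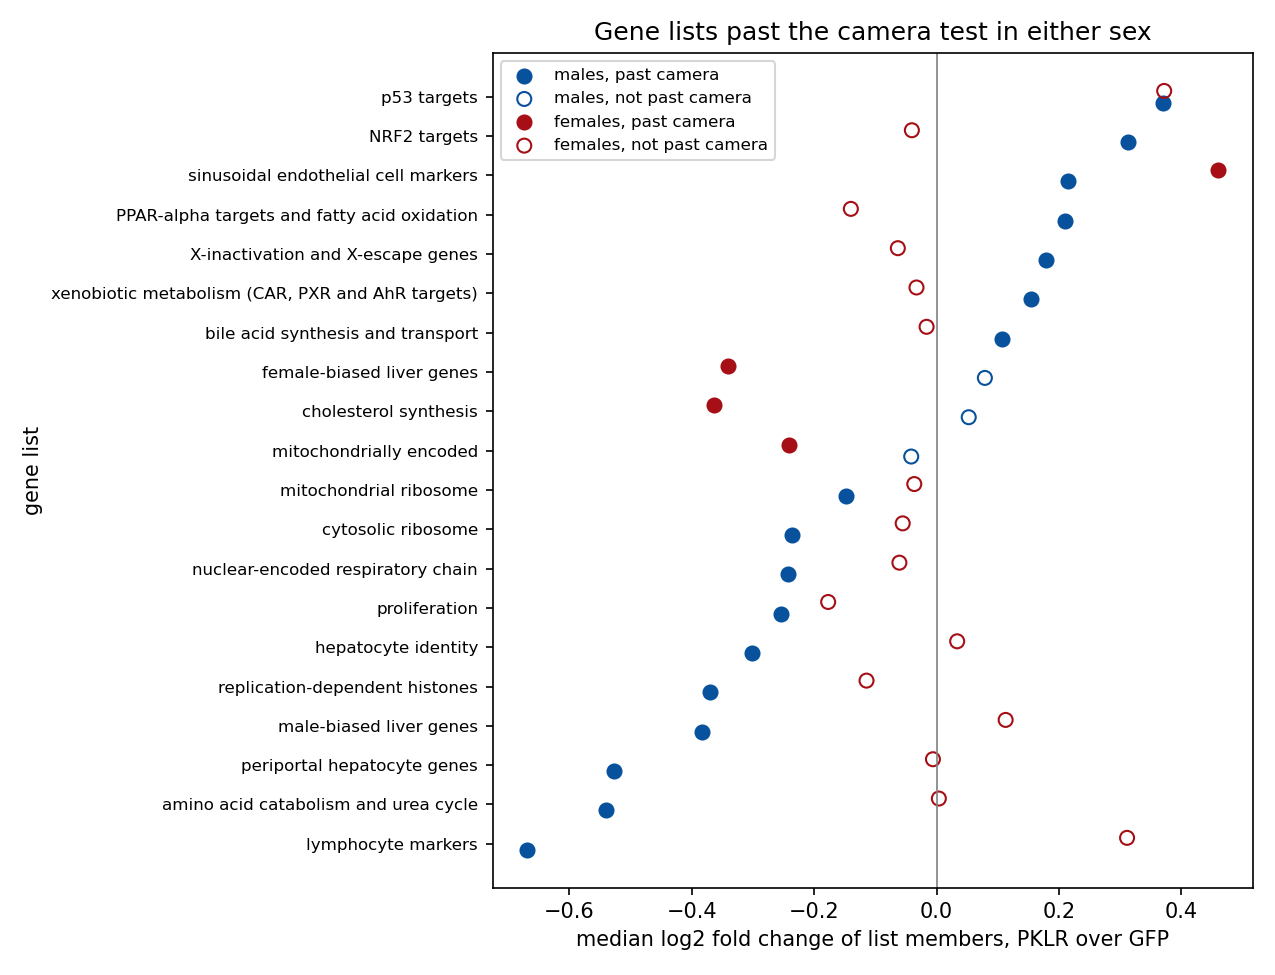
Median log2 fold change of list members with PKLR over GFP (horizontal axis) for each gene list past camera in either sex (vertical axis), males in blue and females in red, with filled points past camera and open points not past it. The amino acid and urea cycle list lies at -0.54 in males, and sinusoidal endothelial markers lie at 0.22 in males and 0.46 in females (0.28 after correction for GC content and length). None of these lists passed with an estimated correlation.

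Among 6 genes of short non-coding RNAs, edgeR called 5 lower with PKLR in females and none of the 6 in males. The falls were of similar size in both sexes. Rn7sk, the 7SK RNA that restrains transcription elongation (chromosome 9, 78175303 to 78175633), fell in females from 62.5 ± 25 CPM to 5.64 ± 2.7 CPM (log2 fold change -3.47, SE 0.652, adjusted p = 0.0312). Rmrp, the RNA of the nuclease RNase MRP (chromosome 4, 43492788 to 43493058), fell in females from 197 to 10 counts over the group, a ratio of 19.1 (95% interval 10.2 to 40.4, adjusted p = 0.0425). In males Rn7sk had a log2 fold change of -3.38 (adjusted p = 0.0963, 82.1 ± 68.6 CPM with GFP and 7.88 ± 4.3 CPM with PKLR). Rmrp in males had 365 counts with GFP and 15 with PKLR, a ratio of 23.1 (95% interval 13.8 to 41.7, adjusted p = 0.0794). Male GFP library 3, which stands apart for short genes, held 234 of the 365 counts of Rmrp, and without it the male log2 fold changes were -3.47 for Rmrp (-4.40 with it) and -2.64 for Rn7sk. Rpph1, the RNA of RNase P, and Gm26315, Gm24447 and Gm26035, which share 95.7% to 100% identity with Rn7sk over 233 to 241 bases, were chosen after their values were seen, as were Rn7sk and Rmrp in males, where the naming rule does not take them. The 3 numbered genes had values of -3.60, -3.54 and -3.65 in females, where all 3 fell (adjusted p = 0.0302, 0.0312 and 0.0302), and -3.76, -3.72 and -3.53 in males (adjusted p = 0.0794, 0.0855 and 0.0857). Rpph1 had -2.42 in males (adjusted p = 0.228, -1.57 without male GFP library 3) and -2.08 in females (adjusted p = 0.15). DESeq2 called Rn7sk, Rmrp and Rpph1 in males (adjusted p = 3.06e-05, 0.000143 and 0.0349) and in females (1.16e-05, 0.00035 and 0.0471). With limma-voom the adjusted p-values of Rn7sk and Rmrp in females were 0.0545 and 0.125. Their edgeR calls in females ended without any 1 female library other than female GFP library 1. Over these 6 genes the median was -3.63 in males and -3.57 in females. The 3 numbered genes may share reads with Rn7sk, so the 6 are not independent and this median may weigh 7SK too heavily.

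**Figure D4:**
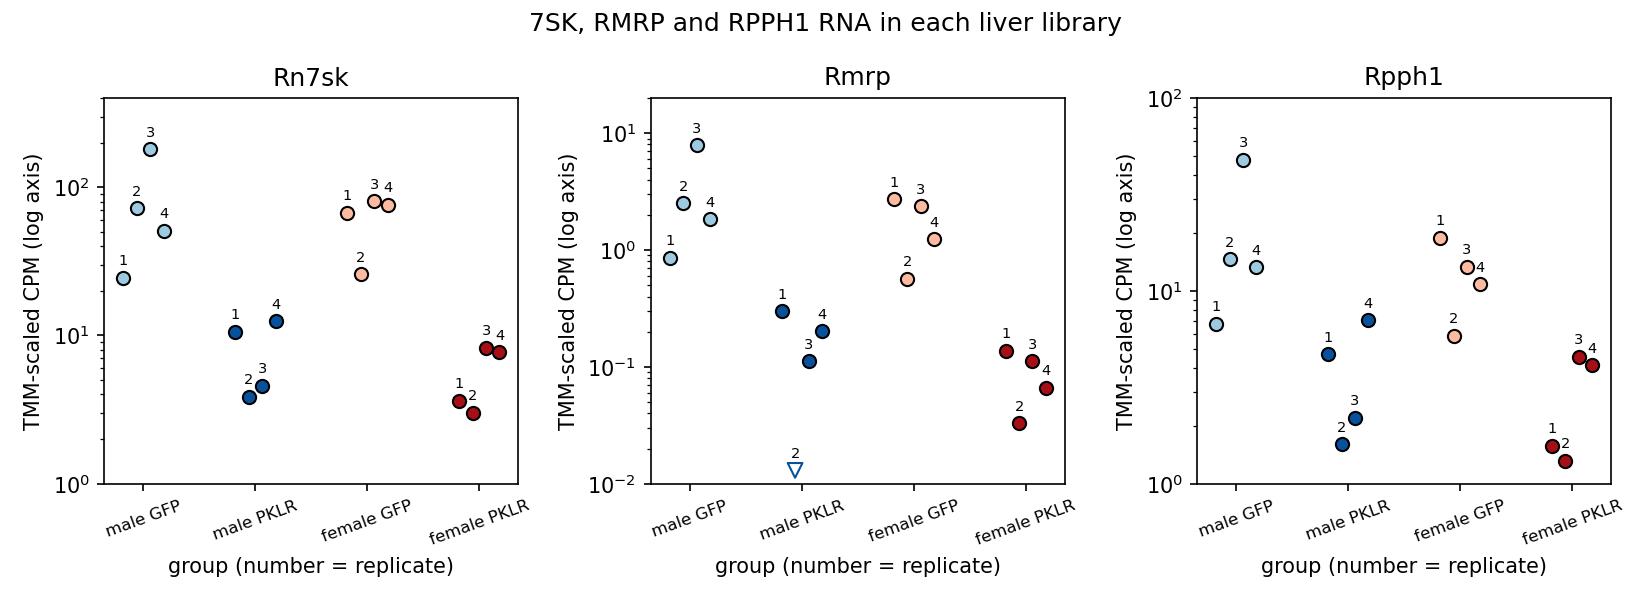
Level of Rn7sk, Rmrp and Rpph1 in TMM-scaled CPM (vertical log axes) in each library of the 4 groups (horizontal axis), with replicate numbers beside the points. The open triangle marks male PKLR library 2, which had 0 Rmrp counts. GFP livers lie at 24.5 to 181 CPM for Rn7sk and PKLR livers at 3.02 to 12.5 CPM.

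The PKLR effect was compared between the sexes by the difference of both effects, given here as female minus male. No gene passed the test for this difference. The smallest adjusted p was 0.199, and 2192 genes had an unadjusted p under 0.05 where chance gives 806. That number can exceed chance without an effect, since genes are not independent. It was 1595 after correction for GC content and length. The difference draws on the female GFP libraries with the tilt on GC content. Its median over coding genes went from -0.21 at a GC content up to 42% to 0.36 above 58%. Values of the single genes below come from the fit without the correction. DESeq2 called 59 higher and 44 lower, and limma-voom 0. Without female GFP library 1 the edgeR test called 308 higher and 130 lower, and without female PKLR library 1 or male PKLR library 1 it called 1. The smallest p-values on the positive side belonged to Sppl2b (0.87), Dact2 (1.35), Wsb1 (1.0), Tspan9 (0.67), Repin1 (0.68) and Kmt5c (0.89). On the negative side stood Nr1i3 (-1.30), Nrp2 (-1.18), the pyruvate dehydrogenase subunit Pdha1 (-0.55), Casc4 (-1.09), Aldh3a2 (-1.06) and Arpp19 (-0.54). All 12 had an adjusted p = 0.199.

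Camera found 16 lists past the test for the difference, and none of them passed with an estimated correlation, where adjusted p-values were 0.784 to 0.97. PPAR-alpha targets had 33 of 35 members below 0 (median -0.42, camera adjusted p = 3.88e-06, adjusted p = 0.816 with an estimated correlation), with Cd36 at -1.89 and Pex11a at -0.86 (each with an adjusted p = 0.224) and 7 members lower adjusted over the list alone. Amino acid and urea cycle genes had 22 of 27 above 0 (median 0.42, camera adjusted p = 0.000164, adjusted p = 0.816 with an estimated correlation), with Got1 at 1.82 (adjusted p = 0.208) and 4 higher adjusted over the list alone. Periportal genes had 15 of 16 above 0 (median 0.51, adjusted p = 0.784 with an estimated correlation), with 5 higher adjusted over the list alone. Genes known to be higher in male liver had 20 of 26 above 0 (median 0.49, camera adjusted p = 0.00185, adjusted p = 0.884 with an estimated correlation), with Gstp1 at 1.14 (adjusted p = 0.199) and Serpina1e at 1.15 (adjusted p = 0.224). Without female PKLR library 1 that median was 0.16. Genes known to be higher in female liver had 23 of 29 below 0 (median -0.45, camera adjusted p = 0.00124, adjusted p = 0.784 with an estimated correlation), with Cyp2b9 at -3.34 (adjusted p = 0.208) and Cyp2b13 at -2.28 (adjusted p = 0.235). Adjusted over the list alone, 1 gene was higher in the former list and 1 lower in the latter. Calls in males and females shared 1 gene, Pklr, where independent lists would share 0.00273. Pklr is the gene that the PKLR vector carries in both sexes, so this overlap checks the labels and shows no shared response. Of the 129 genes called in females, 93 had the same sign in males, where their median was -0.07. Of the 2110 genes at an unadjusted p under 0.05 in males, 1098 (52.0%) had the same sign in females. Across all genes the log2 fold changes of the sexes had a Pearson correlation of 0.118 and a Spearman correlation of 0.0745. Genes are not independent replicates, so no p-value is given.

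With GFP, 1352 genes were higher and 1843 lower in females than in males. After correction for GC content and length 1225 were higher and 1485 lower, and 2027 of the 3195 calls were kept. Named genes with large differences included cytochromes P450, sulfotransferases, major urinary proteins, genes of the sex chromosomes, A1bg, Moxd1 and Tff3. Cyp2b13 averaged 0.146 ± 0.0704 CPM in males and 323 ± 76.3 CPM in females, a ratio of 2220 (95% interval 1346 to 3968, adjusted p = 1.09e-10). Cyp2b9 (log2 fold change 10.42), A1bg (10.32) and Cyp3a41b (8.29) were also higher in females. Sult3a1 and Sult2a4 had 0 counts in males and were at least 1991-fold and 287-fold higher in females, and Sult2a1, Sult2a2 and Sult2a3 had 12, 12 and 1 counts in males against 23391, 23792 and 3084 in females. Cyp4a12a (-9.75), Cyp4a12b (-9.40), the steroid dehydrogenase Hsd3b5 (-8.46), Mup20 (-7.32), Mup-ps19 (-7.32) and Mup5 (-6.07) were lower in females. Moxd1 and Tff3 had 3 counts in females against 3609 and 2824 in males, ratios of 1395 (95% interval 477 to 6768) and 1092 (373 to 5296), and adjusted p-values of 0.0186 and 0.000712. Their male levels varied widely, at 32.1 ± 35.3 and 26.1 ± 27.6 CPM, and without male GFP library 3 the log2 fold changes went from -10.09 to -9.03 and from -9.79 to -8.99. Moxd1 lost its call without any 1 of the female GFP libraries (adjusted p up to 0.0713). Xist had a log2 fold change of 9.91, and Kdm5d, Ddx3y, Uty and Eif2s3y of the Y chromosome had 3 to 8 counts in females. Members of the Sult2a, Cyp2b, Cyp3a41, Cyp4a12 and Mup families are near-identical, so counts of single members are uncertain.

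All 26 members of the list of male-biased liver genes were lower in females with GFP (median -4.23, camera adjusted p = 1.44e-38, adjusted p = 0.00942 with an estimated correlation). Of the 29 female-biased genes, 26 were higher and 1 lower (median 5.02, camera adjusted p = 1.61e-39, adjusted p = 0.000709 with an estimated correlation), and the median was 5.02 also with the 1 member at 0 counts set to its bound. Adjusted over the list alone, the counts were 26 lower in the former and 28 higher and 1 lower in the latter. The Y-linked list (4 of 4 lower) and the X-inactivation list (4 of 5 higher) also passed with an estimated correlation (adjusted p = 0.00135 and 0.0184), and 4 and 5 members were called adjusted over the list alone. The remaining 9 of the 13 lists past camera did not, with adjusted p-values of 0.743 to 0.836 with an estimated correlation. PPAR-alpha targets had 17 of 35 members higher (19 higher and 1 lower adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), among them Acot3 (4.92), Ehhadh (1.0) and Acadl (0.62). Acute phase genes had 8 of 26 higher (10 adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), with Orm3 at 4.04 and complement C3 at 0.83. Genes of the unfolded protein response had 7 of 21 lower (9 adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), with Xbp1 at -0.95, Atf4 at -0.64 and Sdf2l1 at -1.70. Xenobiotic genes had 9 of 22 higher and 2 lower (9 and 3 adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), with Nr1i3 at 1.70 and Cyp2c37 at 2.79. Insulin, glucocorticoid and fasting genes had 6 of 18 higher (7 higher and 1 lower adjusted over the list alone, adjusted p = 0.743 with an estimated correlation), with the metallothioneins Mt1 and Mt2 at 3.23 and 3.94. Single genes of lists that did not pass camera were Klf10 (1.0), Arrdc4 (1.33) and Rgs16 (3.27), all ChREBP targets and higher in females, Prlr (2.52) and Serpina6 (1.23), also higher, and Cyp7b1 of bile acid synthesis (-3.93), lower. Pklr did not pass (-0.17, adjusted p = 0.695).

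The remaining lists past camera with GFP were inflammatory cytokines (3 of 15 higher, 3 adjusted over the list alone, adjusted p = 0.756 with an estimated correlation), cholesterol synthesis (median -0.46, 0 called), the respiratory chain (1 higher and 13 lower of 79) and the mitochondrial ribosome (1 higher and 17 lower of 74), each of the last 3 with an adjusted p = 0.836 with an estimated correlation. Adjusted over the list alone they had 0, 1 higher and 12 lower, and 1 higher and 24 lower. The mitochondrial ribosome median was -0.12 and turned to 0.04 when scaled to total counts, and the respiratory chain median was -0.19, -0.03 with total counts and -0.10 after correction for GC content and length. Genes higher in females with GFP included 237 processed pseudogenes, and coding genes had a mean GC content of 45.7% among those higher and 53.8% among those lower, in the direction of the tilt of female GFP libraries 2, 3 and 4. Scaling to total counts shifted the median of all genes from 0.01 to 0.16 with GFP and to 0.11 with PKLR, and called 2607 higher and 964 lower with GFP.

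With PKLR, 448 genes were higher and 540 lower in females than in males. A1bg averaged 0.548 ± 0.303 CPM in males and 391 ± 218 CPM in females (log2 fold change 9.47, adjusted p = 8.12e-06). Cyp3a41a (7.96), Cyp3a41b (8.05) and Xist (9.28) were higher in females. Sult2a1, Sult2a2, Sult2a3 and Sult2a5 had 12, 11, 1 and 1 counts in males against 10890, 11771, 1340 and 855 in females, and Sult3a2, with 0 counts in males, was at least 99.6-fold higher. Cyp4a12a (-9.57), Cyp4a12b with a ratio of 705 (95% interval 491 to 1053), Hsd3b5 (-6.90), Mup20 (-6.53), Mup-ps19 (-6.69), Mup-ps21 (-6.11) and Mup5 (-5.21) were lower, as were Ddx3y, Kdm5d, Uty and Eif2s3y. Nat8f5 had 449 counts in males and 2 in females, a ratio of 177 (95% interval 48.8 to 1468). Scaling to total counts gave 775 higher and 358 lower, and correction for GC content and length gave 562 higher and 876 lower. Pklr did not pass (-0.73, adjusted p = 0.137).

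Of the male-biased list 24 of 26 genes were lower in females with PKLR (median -3.81, camera adjusted p = 8e-53, adjusted p = 0.00247 with an estimated correlation), and the median did not change with its 1 member at 0 counts set to the bound. Of the female-biased list 27 of 29 were higher (median 4.62, camera adjusted p = 8.3e-55, adjusted p = 0.000135 with an estimated correlation). Adjusted over the list alone, the counts were 26 lower in the former and 27 higher and 1 lower in the latter. The Y-linked list (4 of 4 lower) and X-inactivation list (2 of 5 higher, 5 adjusted over the list alone) passed with adjusted p-values of 0.000141 and 0.0121 with an estimated correlation. Camera found 17 further lists past the test. Genes of MHC class II antigen presentation were higher in females, with 6 of 7 called (7 adjusted over the list alone, median 1.03, adjusted p = 0.232 with an estimated correlation), among them Cd74 (1.10), H2-Eb1 (1.05) and H2-DMb1 (1.08). Acute phase genes had 9 of 26 higher (17 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation), with Lbp at 1.16, C3 at 0.78 and Orm3 at 3.66. NRF2 targets had 10 of 20 lower and 1 higher (12 and 1 adjusted over the list alone, adjusted p = 0.0899 with an estimated correlation), with Gsta1 at -2.45, Ugdh at -1.25, Ephx1 at -0.88 and Gsr at -0.50. Cholesterol synthesis had 25 of 26 below 0 (median -0.84, 2 lower, 15 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation), with Nsdhl at -1.70 and Cyp51 at -1.66. Lipid droplet genes had 4 of 17 lower (5 adjusted over the list alone, adjusted p = 0.332 with an estimated correlation), with Fitm1 at -2.97 and Cidec at -1.88. Unfolded protein response genes had 5 of 21 lower (7 adjusted over the list alone, adjusted p = 0.232 with an estimated correlation), with Hyou1 at -1.13 and Hspa5 at -0.85.

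Growth hormone and STAT5 genes had 4 of 12 higher in females with PKLR (7 higher and 2 lower adjusted over the list alone, adjusted p = 0.0899 with an estimated correlation), with the prolactin receptor Prlr at 2.0 and the cytokine inhibitor Socs2 at 1.64. Insulin, glucocorticoid and fasting genes had 4 of 18 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.374 with an estimated correlation), with Mt1 at 3.61. Amino acid and urea cycle genes had 22 of 27 above 0 with 2 called higher and 1 lower (4 and 2 adjusted over the list alone, adjusted p = 0.708 with an estimated correlation), and Got1 was higher by 1.40, at 180 ± 9.73 CPM in females and 68.4 ± 8.9 CPM in males. The other 8 lists past camera had medians of -0.51 (adipocyte markers, -2.27 with DESeq2), -0.31 (pentose phosphate and NADPH), -0.22 (mitochondrial genome, -0.12 after correction for GC content and length), 0.12 (cytosolic ribosome, 0.22 with total counts), 0.20 (matrix and stellate cell markers), 0.25 (sinusoidal endothelial markers), 0.36 (inflammatory cytokines) and 0.59 (macrophage markers). Their adjusted p-values were 0.232, 0.232, 0.374, 0.827, 0.708, 0.648, 0.378 and 0.595 with an estimated correlation. The DESeq2 median of adipocyte markers was taken without the filter on low counts. It can hold members that the edgeR median leaves out, so these medians are not like for like. Markers of stellate, sinusoidal endothelial and macrophage cells had 25 of 30, 18 of 18 and 21 of 24 above 0.

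**Figure D5:**
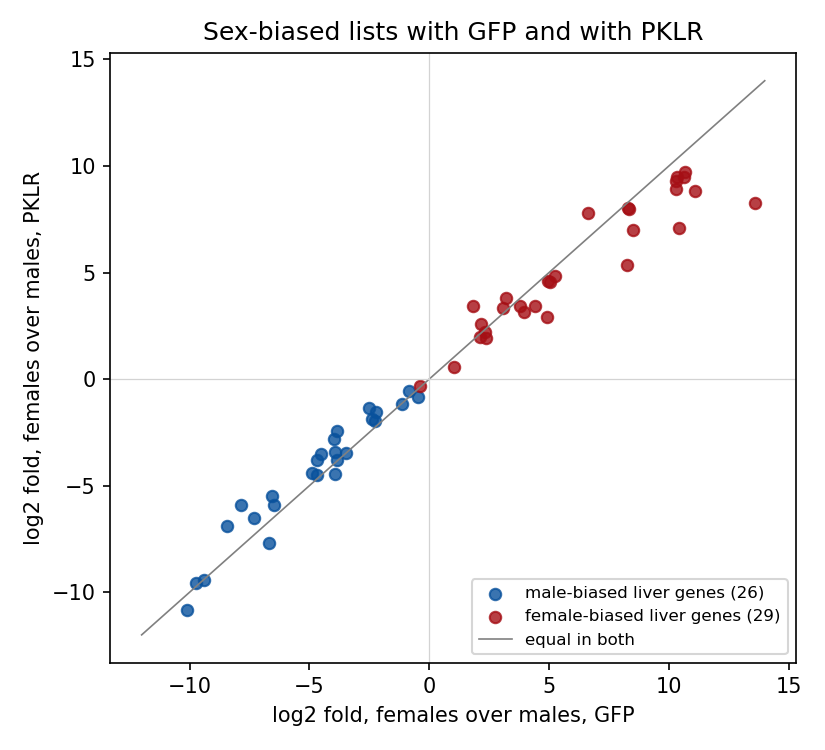
Fitted log2 fold change of females over males with GFP (horizontal axis) and with PKLR (vertical axis) for the 26 male-biased genes (blue) and 29 female-biased genes (red), with a line where both are equal. Medians are -4.23 and -3.81 for the male-biased list and 5.02 and 4.62 for the female-biased list. Some fitted values beyond 10 rest on few or 0 counts in one sex.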

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

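Tests chosen after the result was seen are those on GC content and length, on the shift of 3 female GFP libraries, on other short RNAs, on batches, on mixed samples and on other splits for counts of genes and lists, while those on pseudogene parents, on single libraries and on the gap between the sex-biased lists were written first.

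Most of the 85 genes lower in female PKLR livers were processed pseudogenes (60), and the 44 higher included Pklr, which was 1.48 after the correction below. With the trend on GC content and length removed, the median of the 44 went from 0.54 to 0.27 and that of the 85 from -1.45 to -1.10, and no gene was called (edgeR, 1658 at an unadjusted p under 0.05). Of the 60 pseudogenes, 54 had a parent at least 90% identical and 10 times as abundant. Over all 60 the parents had a median of -0.13 against -1.45, which met the prediction written for stray reads of parents. Straying at a fixed share would give the pseudogenes the change of their parents. Stray reads would thus give this gap only if their share differed between libraries, which was not tested. A change of the pseudogenes themselves would give the same values, so the test cannot tell it from stray reads. Female GFP library 1 lay at 18.1% of the distance of the other 3 from the PKLR mean for the lower genes and at 61.7% for the higher ones, so a shift shared by libraries 2, 3 and 4 may account for much of the lower genes as a set, and the higher ones are not settled by it. Of 35 splits of the females, the real one included, 3 gave as many genes (129, highest other 318), so chance is not excluded, and splits joining those 3 libraries with PKLR library 2 or 1 gave 318 and 141, which points to a structure of the samples, though those with PKLR library 3 or 4 gave 0 and 0.

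The 6 genes of the 7SK, RMRP and RPPH1 RNAs were lower with PKLR by a median of -3.63 in males and -3.57 in females. Rn7sk and the numbered genes like it may share reads, so the 6 are not independent. A general loss of short RNAs is argued against by 36 other short non-coding genes, with medians of -0.19 in males and -0.07 in females. Their values ran from -0.78 to 0.92 in males and from -1.69 to 0.60 in females. That set was open to mitochondrial transfer RNAs and other kinds of RNA, so a loss confined to RNAs like the 6 was not tested. A trend on GC content and length is argued against as the whole cause, since medians stayed at -3.29 in males and -3.47 in females after its removal. The sources used here name no batches, so a batch that follows the vector stays open, and that at least 5 of the 6 genes lay apart in each sex restates the pattern and does not decide it. An effect of PKLR or of the vectors themselves was not tested.

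In the interaction the male-biased list had a median of 0.49 and the female-biased list -0.45, each toward a smaller sex bias with PKLR. After removal of the trend the medians were 0.56 and -0.32, which argues against it for the former list and leaves the latter open. No library went against its label (0 of 16), which argues against a mixed sample. Without female PKLR library 1 the male-biased median was 0.16, so a single library may carry much of it, while the female-biased median was -0.36 without male PKLR library 4, the smallest of those fits. Of 100 groupings, the real one included, 8 gave as large a gap between the lists (0.943, highest other 1.49), so chance is not excluded.

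Counts of splits here include the real one. In males 5 of 35 gave as many genes (1, highest other 5) and 6 of 35 as many lists (17, highest other 19), and in females 34 of 35 gave as many lists (4, highest other 25), so chance is not excluded. For the interaction 26 of 100 gave as many lists (16, highest other 25), so chance is not excluded either. For genes in the interaction the real count was 0 (edgeR, 2192 at an unadjusted p under 0.05, DESeq2 103 and limma-voom 0, highest other 4), so that 100 of 100 had to reach it and the splits say nothing. For sex, the real split was the 1 of 35 with as many genes with GFP (3195, highest other 392). The same held with PKLR (1 of 35, 988, highest other 1), so chance alone is unlikely for both counts. The lowest share that 35 splits can give is 1 of 35, and no adjustment was made over the comparisons. Splits do not separate sex from the tilt of female GFP libraries 2, 3 and 4, which the GFP count may hold. As many lists came from 21 of 35 splits with GFP (13, highest other 23) and from 8 of 35 with PKLR (21, highest other 31), so chance is not excluded for the lists. With GFP the splits with 392, 256 and 239 genes exchanged female GFP library 1 with male GFP library 4, 3 or 2, which points to a structure of the samples, though the exchange with male GFP library 1 gave 0.

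Single libraries stood far from the other 3 of their group in 18 of 377 groups tested (4.78%), where chance gives about 1 in 20. The 377 include ages from the labels, which are equal in all mice and could not be flagged. They also pool library measures with single genes. All library measures flagged were of male GFP library 3 or female GFP library 1, so the pooled share does not show that these differ by chance. Male GFP library 3 had 0.515 for GC-rich minus GC-poor genes (median of the others 0.051), 0.752 for short minus long genes (0.0087), 0.146 for the called pseudogenes (-0.256), 23.7 CPM of Ddx3y (46.2) and 19.5 CPM of Mt1 (8.56). Female GFP library 1 had 0.0673 for GC-rich minus GC-poor genes (-0.423), 0.0142 for all processed pseudogenes (0.203), -0.121 for the called ones (1.23) and 3.18 CPM of Rpl31-ps10 (7.97). Other female GFP libraries had 14 CPM of Gm26315 in library 2 (42.2), 226 CPM of Acadl in library 3 (277) and 88.1 CPM of Sult3a1 in library 4 (47.8). Female PKLR libraries had 394 CPM of Prlr in library 1 (302), 7.18 CPM of Abca7 (9.86) and 32.5 CPM of Sult2a3 (5.64) in library 2, and 47.2 CPM of Map3k11 in library 4 (42.1). Male PKLR libraries had 752.6 CPM of Pklr in library 3 (1075) and 11 CPM of Cyp3a41a in library 4 (6.18).

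The 16 lists that differed in the interaction by camera follow, with the median, female minus male effect, and the adjusted p with an estimated correlation. Metabolic lists were PPAR-alpha targets -0.42 (0.816), amino acid and urea cycle 0.42 (0.816), NRF2 targets -0.33 (0.784), xenobiotic metabolism -0.32 (0.784), cholesterol synthesis -0.47 (0.97) and bile acids -0.25 (0.784). Organelle lists were the cytosolic ribosome 0.19 (0.97; 0.10 after correction for GC content and length), the mitochondrial ribosome 0.15 (0.97), the respiratory chain 0.20 (0.97) and the mitochondrial genome -0.22 (0.816), the last at 0.01 after correction for GC content and length. Cell and sex lists were periportal genes 0.51 (0.784), hepatocyte identity 0.37 (0.784), MHC class II 0.67 (0.816), lymphocyte markers 0.81 (0.816), female-biased genes -0.45 (0.784) and male-biased genes 0.49 (0.884). The 3 lists of both ribosomes and the respiratory chain lost their camera call without male GFP library 3 (adjusted p up to 0.743, 0.492 and 0.701), and the respiratory chain also without female PKLR library 2. Cholesterol synthesis lost it without male GFP library 4, male PKLR library 3, female GFP library 1 or female PKLR library 3 or 4 (up to 0.304), and bile acids without male GFP library 1, male PKLR library 1, female GFP library 1 or female PKLR library 3 or 4 (up to 0.156). Lymphocyte markers lost it without male GFP library 2, male PKLR library 1, female GFP library 1 or female PKLR library 3 (up to 0.177), and MHC class II without female PKLR library 3 (0.0533).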

How the results depend on the processing

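Chosen after seeing the data were the correction for GC content and length and the fit without female GFP libraries 2, 3 and 4. That fit leaves 1 female GFP library, with its spread taken from the other groups, so its low counts of calls say little about those 3 libraries. Counts of genes with PKLR were few and moved most, and where a value below differs from the one in the report the cause was not tested, except that fits with fewer libraries or genes have less data. In males, where 1 gene was higher and 0 lower, DESeq2 gave 73 and 71, no filter on low counts 4 and 2, the 2 male groups alone 2 higher, the replicate block 2 lower, and both the fit without Pklr and the 20 most abundant genes and the GC content and length correction 0 higher. Without male GFP library 1, 2 or 4 there were 2, 2 and 3 higher and 7, 5 and 6 lower, without male PKLR library 1 or 3 there were 2 higher, and without male GFP library 3 or male PKLR library 2 or 4 there were 0. In females, with 44 and 85, total counts gave 230 higher, DESeq2 275 and 286, limma-voom 7 and 4, the block 0 and 7, the female groups alone 0 and 0, the correction 0 and 0, and the fit without female GFP libraries 2, 3 and 4 0 and 1. Without female GFP library 1 there were 780 and 563, without female PKLR library 1 there were 1 and 0, without female PKLR library 2 there were 39 and 59, and without female GFP library 2, 3 or 4 or female PKLR library 3 or 4 there were 0 and 0. For the interaction, with 0 and 0, DESeq2 gave 59 and 44, and leaving out female GFP library 1 gave 308 and 130, female PKLR library 1 gave 1 higher and male PKLR library 1 gave 1 lower. For sex with GFP, with 1352 and 1843, total counts gave 2607 and 964, the GFP groups alone 1177 lower, and the fit without female GFP libraries 2, 3 and 4 275 and 157, and lower genes were 2324 without female GFP library 1 and 1170, 1213 and 1224 without female GFP library 2, 3 or 4. For sex with PKLR, with 448 and 540, total counts gave 775 and 358 and the correction 876 lower. Lists past the test were 0 with an estimated correlation and 0 by fry for PKLR in males, in females and for the interaction, and 4 with an estimated correlation for sex with either vector. Lists with PKLR in females (4) numbered 15 without female GFP libraries 2, 3 and 4, 8 without library 2 of female GFP, 11 without female PKLR library 2 and 7 without female PKLR library 4. Lists were not recomputed under every alternative. With total counts, medians that moved over 1.5 times beside those in the report were bile acids 0.21, xenobiotic metabolism 0.25, hepatocyte identity -0.20, proliferation -0.15 and X-inactivation 0.27 with PKLR in males, the mitochondrial ribosome 0.10 in the interaction, the unfolded protein response -0.24 for sex with GFP, and lipid droplets -0.16 and the mitochondrial genome -0.12 for sex with PKLR. Pklr was higher with PKLR in both sexes under each alternative run, with log2 fold changes of 2.01 to 2.45 in males and 1.44 to 1.85 in females without 1 library. It missed the threshold in males after the correction (2.23, adjusted p = 0.0513) and without male GFP library 3 (2.10) or male PKLR library 2 (2.16) or 4 (2.15). In females it missed it with the female groups alone (1.63), with the block (1.61), after the correction (1.48), without female GFP libraries 2, 3 and 4 (2.02), and without female GFP library 2 (1.63), 3 (1.85) or 4 (1.55) or female PKLR library 1 (1.44), 3 (1.77) or 4 (1.72). The overlap of calls between the sexes (1) was 7 with DESeq2 and 0 with the groups alone, the block, the fit without Pklr and the 20 most abundant genes, the correction and the fit without female GFP libraries 2, 3 and 4, and 0 to 5 without 1 library. The correlation of the effects (0.118) was 0.147 with the groups alone and 0.0414 to 0.152 without 1 library. Directions reversed in 2 values that did not pass, Pkm with PKLR in males under total counts (0.016) and Pklr by sex with GFP without male GFP library 2 (0.088). Pklr by sex with GFP (-0.17) was -0.38 without female GFP library 3. Of the named genes, leaving Pklr with PKLR apart, 8 of 35 in males, 6 of 36 in females, 4 of 20 for the interaction, 29 of 41 for sex with GFP and 35 of 44 for sex with PKLR kept direction and side of the threshold in every alternative that could be run for them. In males 26 and for the interaction 16 passed in some alternative after missing in the main fit. In females 25 missed in some alternative after passing, and 5 passed after missing. For sex 11 with GFP and 9 with PKLR missed after passing. Replicate numbers as a block are not a pairing that the design gives, and 24 pairs of libraries with the same number had correlations of -0.188 to 0.225 (median -0.0184), with 0 of 16 libraries closest to their own number.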

Other observations

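Chosen after the result was seen were the values by library and by biotype below. Rn7sk lay at 24.5 to 181 CPM in the 4 male GFP livers and at 25.9 to 80.7 CPM in the 4 female GFP livers. Genes lower in females with GFP included 61 processed pseudogenes, and with PKLR there were 12 among the genes higher and 14 among the genes lower in females. The median of the mitochondrial transfer RNAs was 0.86, 0.70 and 0.55 in female GFP libraries 2, 3 and 4 and -0.12 in female GFP library 1. Mitochondrial genes held 7.29% to 9.81% of the counts of a library, and the 20 most abundant genes held 21.9% to 27.5%. The first principal component carried 46% of the variance and the second 9.94%.

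Some lists past camera lost that call when 1 library was left out, with the highest adjusted p given. With PKLR in males these were bile acids without male GFP library 1 or male PKLR library 1 (0.113), xenobiotic metabolism without male PKLR library 1 (0.0586), sinusoidal endothelial markers without male GFP library 2 (0.158), and lymphocyte markers (0.324) and proliferation (0.237) without male GFP library 2 or 4 or male PKLR library 1. Histones lost it without male GFP library 3 (0.0867), and X-inactivation genes without male GFP library 3 or male PKLR library 2, 3 or 4 (0.125). For sex with GFP these were the respiratory chain (0.409) and mitochondrial ribosome (0.269) without male GFP library 3, xenobiotic metabolism without male GFP library 1 or 3 (0.0682), cholesterol synthesis without male GFP library 1 or female GFP library 2 (0.141), cytokines without male GFP library 1 or 4 or female GFP library 2 (0.107), and insulin and fasting genes without female GFP library 1 (0.124). For sex with PKLR these were pentose phosphate and NADPH without male PKLR library 3 or female PKLR library 1 or 4 (0.0668), and amino acid and urea cycle genes without male PKLR library 3 or female PKLR library 2 (0.258). Matrix and stellate markers lost it without male PKLR library 1 or 2 (0.246), macrophage markers without female PKLR library 3 (0.0578) and sinusoidal endothelial markers without male PKLR library 1 (0.0699). Among single genes of that comparison, the calls of Nsdhl (up to 0.13), Cyp51 (0.134), Hspa5 (0.0984) and Got1 (0.0511) ended without 1 library. For Nsdhl these were male PKLR library 1 or 3 or female PKLR library 3 or 4, for Cyp51 the same and female PKLR library 2, for Hspa5 male PKLR library 1 or 3 or female PKLR library 1, 2 or 4, and for Got1 male PKLR library 3.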
